A study of Homo sapiens with 12 samples.

How the data were processed

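Total RNA of NB4 cells was labelled as biotinylated cDNA and hybridised to Affymetrix ST arrays, 12 in all. The deposited values are on a log2 scale, and RMA and limma are named as the tools, per the submitters' processing notes, without versions or settings. The log2 unit was checked on the values, which ran from 2.67 to 14.63 with array medians of 7.73 to 7.81. Lower quartiles ran from 6.38 to 6.49 and upper quartiles from 9.11 to 9.28, so the arrays had similar but not identical distributions. The values were used as deposited, with no further normalization. For arrays, their number limits the precision of each value.

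Samples were grouped by the labels. Wild type and scrambled shRNA cells formed the control arms, and shRNA1 and shRNA2 cells the knockdown arms, untreated or after 96 hours of 0.5 uM ATRA, with 3 arrays in each of 4 arms. The lines with an shRNA were stable, sorted for GFP and derived from single cells, per the labels' design text. That text calls the duplicates of scrambled and shRNA1 cells biological but does not say whether they came from separate clones, and each numbered duplicate is counted below as a line of its own only for convenience. The p values therefore measure the spread between these samples, part of which may be technical. Line and knockdown state cannot be separated by a model, since each line is either control or knockdown.

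Genes were named through the platform annotation, matched to current symbols by Entrez identifier. Of the probe sets, 19158 had 1 gene, 1388 had several and 11775 were not listed. Only those with 1 gene were used, 19128 of them with a matched identifier, and 0 symbols changed. Where a gene had more than 1 probe set (637 genes), the one with the highest mean over the 12 arrays was kept, which gave 18404 genes. No probe set was removed for a low value. HOTAIRM1 has no named probe set, so the knockdown itself could not be checked.

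Differences were tested with limma 3.58.1 in R 4.3.3, by lmFit on a model of 4 arm means and eBayes with its default settings, with 8 residual degrees of freedom. The contrasts were ATRA against untreated in control cells and in knockdown cells, knockdown against control in each state, and the difference between the ATRA responses. P values were two-sided and adjusted by Benjamini-Hochberg over the genes tested within each contrast, with a threshold of 0.05. Signs are ATRA minus untreated and knockdown minus control. Standard errors are those of the moderated fit. An exact permutation test of 3 against 3 arrays cannot give a two-sided p below 0.1, so single genes were tested with the model alone.

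The comparisons, the alternatives, 22 gene lists and the rule for named genes were fixed before the data were examined. The lists covered the HOXA cluster, integrins, retinoid metabolism and direct targets, oxidase and neutrophil receptors, secondary and tertiary granules, primary granules, myeloid transcription factors, S phase, G2 and mitosis, CDK inhibitors and G1, the DNA damage response, ribosome biogenesis, the interferon response, chemokines and cytokines, apoptosis, autophagy and lysosome, coagulation and fibrinolysis, and markers of monocytes, lymphoid cells, erythroid cells and progenitors, with housekeeping genes. Lists with at least 3 measured members (21) were tested against all other genes with camera from limma, with its preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 21 lists of a contrast. The correlation estimated from the data was the alternative, and no list call passed an adjusted p of 0.05 with it. Genes are called measured where they had a probe set with 1 gene. Of the 11 HOXA genes listed, 1 was measured in this sense.

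Named genes were the HOXA genes measured and, among genes past the threshold whose 3 arrays of 1 arm all lay above the 3 of the other, the 8 with the largest rise and the 8 with the largest fall. For the difference in response, the same was asked of the changes per line, with untreated and ATRA arrays matched by shRNA and replicate number. Where fewer than 3 passed in a direction, the 5 with the smallest p were taken. Up to 4 members with the smallest p were added for each list with a called member or a passed list test and, whether or not they passed, for integrins, S phase, G2 and mitosis, CDK inhibitors and G1, myeloid transcription factors, and oxidase and neutrophil receptors. Genes of families with shared sequence, such as the interferon-induced, olfactory receptor and melanoma antigen genes, and pseudogenes are uncertain, since probes can bind several members.

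The size of the response was the mean change of knockdown lines divided by that of scrambled lines, signed by the wild type direction, over genes that moved by at least 1 on the log2 scale in the wild type pair. The shRNAs were compared by the share of the 200 top genes of shRNA1 against scrambled cells for which shRNA2 against wild type cells had the same sign, with an exact Clopper-Pearson interval of 95%. The interval treats genes as independent, which they are not.

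The fit was tested on 20 simulated datasets of 18404 genes with 200 changed genes. For knockdown against control after ATRA it recovered 56.4% of genes changed by 0.5 on the log2 scale, 95.2% of those changed by 1 and 99.1% of those changed by 2, with 8.3 false calls per dataset. For the difference in response it recovered 18.4%, 84.3% and 97.8%, with 6.6 false calls. For untreated cells, where nothing was changed, it made 0.15 false calls per dataset. A shifted list was found in 20 of 20 datasets, with 0.1 other lists past the threshold on average. The simulated noise was independent between genes. It was also normal, with 1 variance per gene in all arrays, so no simulated array stood apart. These datasets therefore cannot show how the tests behave with correlated genes or an outlying array, as in the real data. The recovery rates need not hold there. Of 45 S phase genes with a mean difference of 0.508 between knockdown and control cells after ATRA, 1 was called over all genes.

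The alternatives were the fit on the arrays compared alone, leaving out each array, the wild type arrays, the shRNA2 arrays or both, quantile normalization, median centring, removal of the lowest 33.3% of genes by mean value, the mean of a gene's probe sets, a trended and robust variance, array weights, a log2 change of at least 1 as a further threshold, line as a block in the ATRA contrasts and the difference, replicate number as a block over scrambled and shRNA1 arrays in the knockdown contrasts, and line as a random block in the latter. Olfactory receptor genes (340), the gene families of the closing section and the tests of explanations there were chosen after the data were seen.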

Results

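Gene expression was measured on 12 Affymetrix ST arrays, each hybridised with total RNA of NB4 cells, a human acute promyelocytic leukemia line that matures toward granulocytes under all-trans retinoic acid (ATRA). The arrays cover 4 kinds of cells, each before and after 96 hours of 0.5 uM ATRA. Control cells were wild type NB4 (1 array in each state) and cells with a scrambled shRNA (2 arrays in each state). Knockdown cells carried shRNA1 (2 arrays in each state) or shRNA2 (1 array in each state) against HOTAIRM1, a long noncoding RNA transcribed from the HOXA gene cluster. Control and knockdown cells in each state make 4 arms of 3 arrays. Log2 values ran from 2.67 to 14.63, and array medians from 7.73 to 7.81. The number of arrays limits the precision. At most 8 values were identical in any pair of arrays, and Pearson's r across genes within an arm lay between 0.979 and 0.995.

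HOTAIRM1 has no probe set under its name in the annotation used, so its level in the knockdown cells was not checked here. HOXA2 was the only one of the 11 HOXA genes listed with a probe set annotated to 1 gene alone. The others were left out by this rule, so any values the arrays hold for them were not examined. HOXA transcription factors pattern the body axis and act in early blood cells. HOXA2 lay at 6.86 ± 0.08 (SD, n = 3) in untreated control cells and 6.85 ± 0.16 in untreated knockdown cells. After ATRA it lay at 7.14 ± 0.17 and 7.19 ± 0.08 (SD, n = 3 each). Its log2 change with ATRA was 0.27 in control cells (adjusted p = 0.0571, limma), and it rose by 0.33 in knockdown cells (adjusted p = 0.0357). Between knockdown and control cells HOXA2 differed by -0.01 before ATRA (adjusted p = 0.999) and 0.05 after it (adjusted p = 0.776).

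ATRA separated the arrays along principal component 1, which held 66.7% of the variance. Control arms had mean scores of -25.4 ± 12.9 untreated and 38.2 ± 4.82 after ATRA (SD, n = 3 each). Knockdown arms had mean scores of -37.1 ± 3.60 and 24.3 ± 3.60. The untreated scrambled replicate 2 array scored -10.6, while the other untreated arrays scored between -41.2 and -32.5. TGM2, a transglutaminase induced by retinoic acid, stood at 12.86 in that array against 7.93 to 8.30 in the other untreated arrays. ITGAM, the alpha M integrin subunit of mature myeloid cells, stood at 10.16 there against 7.31 to 8.56.

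**Figure D1:**
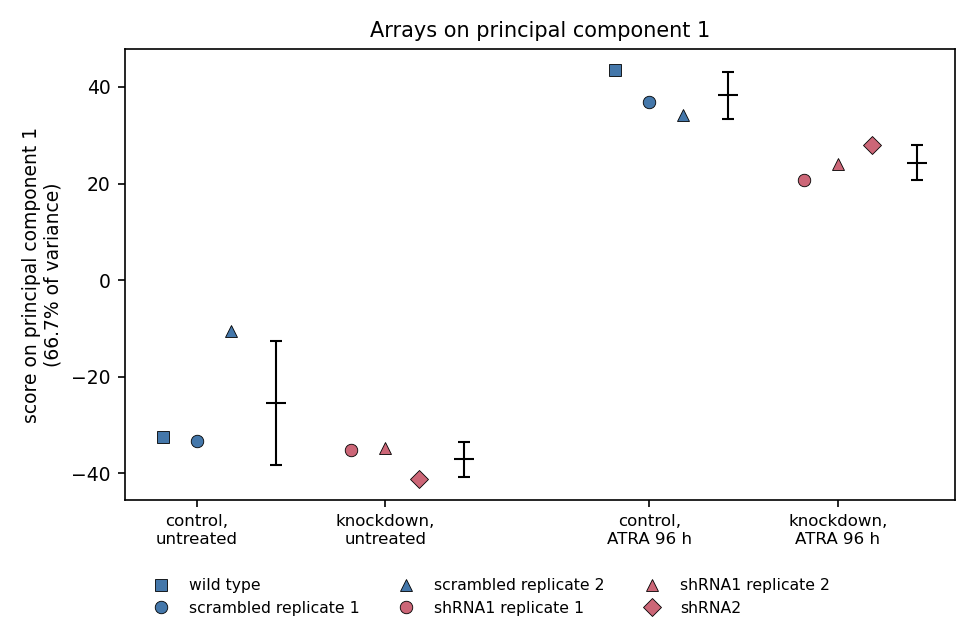
Score of each of the 12 arrays on principal component 1 (y axis, no unit, 66.7% of variance) by arm (x axis), with blue control and red knockdown arrays and black bars for the arm mean and SD. The 3 knockdown arrays after ATRA score 20.8 to 28.0, below the 3 control arrays after ATRA at 34.2 to 43.5, and the untreated scrambled replicate 2 array at -10.6 lies above the other untreated arrays.

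The first comparison asks which genes change when control NB4 cells are given ATRA. ADGRE3, an adhesion receptor of mature myeloid cells (probe set 8034851), rose 20.1-fold, from a log2 level of 7.69 ± 0.81 to 12.02 ± 0.19 (SD, n = 3 each). AQP9, a channel for water and small solutes, rose by 4.91 on the log2 scale (SE 0.40), and JAML, an adhesion molecule of neutrophils and monocytes, by 4.06 (SE 0.37). THBS1, the secreted adhesion protein thrombospondin, rose by 4.21 (SE 0.39) and TGM2 by 3.98 (SE 0.91). CST7, an inhibitor of cathepsin proteases, fell by 2.10 on the log2 scale (SE 0.23), and the cell cycle transcription factor E2F5 fell by 2.24 (SE 0.42). Other genes with large changes were IGSF6, LRRK2 and OAS1, which rose by 3.84 to 4.33, and IFT57, MTSS2, EBF3, CHRNA5, TENT5C and the uncertain pseudogene RNASE2CP, which fell. Among 18404 genes, limma called 2800 higher and 3844 lower at an adjusted p under 0.05, and 8648 had an unadjusted p under 0.05. A change of at least 1 on the log2 scale was found in 412 of the higher and 481 of the lower genes. Of 340 olfactory receptor genes, which myeloid cells are not known to use, 44 were called higher and 1 lower. They lie near the floor, so part of the higher calls may follow a shift of dim genes. How large that part is was not tested. Fewer genes were called higher without the wild type untreated array (1549), the wild type ATRA array (1783) or both (983), and 4450 were with array weights. The rise of TGM2 was 5.52 without untreated scrambled replicate 2, 3.24 without untreated scrambled replicate 1 and 3.17 without untreated wild type cells, and its call was lost without the wild type arrays, at 3.23 (adjusted p = 0.0563).

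Genes of DNA replication and cell division fell with ATRA in control cells. Of the 45 measured S phase genes, 44 fell, over all genes and also adjusted over the list alone, with a mean log2 change of -1.02 (camera adjusted p = 3.32e-25; adjusted p = 0.0791 with an estimated correlation). DSCC1, a gene of DNA replication and sister chromatid cohesion, fell by 1.64 (SE 0.13), and the replication fork subunit GINS3 fell by 1.44 (SE 0.12). Of the 38 G2 and mitosis genes, 34 fell and 35 did adjusted over the list alone, with a mean of -0.78 (adjusted p = 5.94e-15; adjusted p = 0.156 with an estimated correlation). The phosphatase CDC25A fell by 1.54 (SE 0.17) and the spindle checkpoint gene MAD2L1 fell by 1.25 (SE 0.12). Of the 19 DNA damage response genes, 16 fell and 2 rose, and 17 and 2 did adjusted over the list alone, with a mean of -0.75 (adjusted p = 8.02e-08; adjusted p = 0.0645 with an estimated correlation). The exonuclease EXO1 fell by 1.58 (SE 0.11) and the checkpoint kinase CHEK1 fell by 1.12 (SE 0.10). All 19 ribosome biogenesis genes fell, over all genes and adjusted over the list alone, with a mean of -1.08 (adjusted p = 6.81e-12; adjusted p = 0.144 with an estimated correlation). WDR12 fell by 1.51 (SE 0.18) and POLR1B, a subunit of RNA polymerase I, fell by 1.44 (SE 0.17).

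Genes of mature myeloid cells and of the interferon response rose with ATRA in control cells. Of the 25 interferon response genes, 21 rose and 22 did adjusted over the list alone, with a mean of 1.97 (adjusted p = 4e-09; adjusted p = 0.242 with an estimated correlation). TRIM22 rose by 2.99 (SE 0.48) and IRF9, a subunit of the interferon-activated transcription factor, by 2.17 (SE 0.22). Of the 16 genes of the oxidase and neutrophil receptors, 10 rose and 13 did adjusted over the list alone, with a mean of 1.0 (adjusted p = 1.59e-05; adjusted p = 0.144 with an estimated correlation). The complement receptor C5AR1 rose by 2.51 (SE 0.35) and the IgA receptor FCAR by 1.99 (SE 0.21). Of the 25 chemokines and cytokines, 12 rose and 13 did adjusted over the list alone (mean 0.96, adjusted p = 0.000113; adjusted p = 0.112 with an estimated correlation), with IL1B at 3.12 (SE 0.25) and CXCL8, a chemoattractant of neutrophils, at 2.48 (SE 0.30). Of the 18 monocyte and macrophage markers, 9 rose and 12 did adjusted over the list alone (mean 0.62, adjusted p = 5.13e-05; adjusted p = 0.0645 with an estimated correlation), with the costimulator CD86 at 2.59 (SE 0.30). The median change of 340 olfactory receptor genes, which myeloid cells are not known to use, was 0.12 in the same comparison.

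Of the 26 autophagy and lysosome genes, 14 rose and 2 fell in control cells, and 14 and 3 did adjusted over the list alone (mean 0.57, adjusted p = 0.00041; adjusted p = 0.198 with an estimated correlation), among them the cholesterol carrier NPC2 at 1.78 (SE 0.26). Of the 19 genes on the list of secondary and tertiary granules, 9 rose and 1 fell, and 10 and 1 did adjusted over the list alone (mean 0.95, adjusted p = 0.00442; adjusted p = 0.104 with an estimated correlation), with S100A12 at 3.16 (SE 0.68; 4.17 without wild type ATRA and 2.53 without scrambled replicate 1 ATRA) and S100A8 at 2.61 (SE 0.60). This list also holds S100A8, S100A9, S100A12 and BPI, whose proteins are not specific to these granules. Of the 18 genes of retinoid metabolism and direct targets, 9 rose and 2 fell, and 10 and 2 did adjusted over the list alone (mean 0.96, adjusted p = 0.00542; adjusted p = 0.144 with an estimated correlation). The receptor RARB rose by 2.46 (SE 0.33), while the retinol dehydrogenase RDH10 fell by 1.34 (SE 0.15). The list test was not passed by integrins (adjusted p = 0.0883), primary granules (0.202), myeloid transcription factors (0.16), CDK inhibitors and G1 (0.927), apoptosis (0.329), coagulation and fibrinolysis (0.16), lymphoid markers (0.16), erythroid and megakaryocyte markers (0.378), progenitor and stem markers (0.928) or housekeeping genes (0.0792). Among the integrins, ITGAX rose by 2.48 (SE 0.36) and ITGAM by 1.73 (SE 0.41), and ITGA5 fell by 1.46 (SE 0.17). Without the untreated scrambled replicate 2 array, integrins passed at a mean of 0.58 (adjusted p = 0.0161) and myeloid transcription factors at 0.47 (adjusted p = 0.0151). Without the wild type ATRA array, integrins passed at 0.50 (adjusted p = 0.0286).

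**Figure D2:**
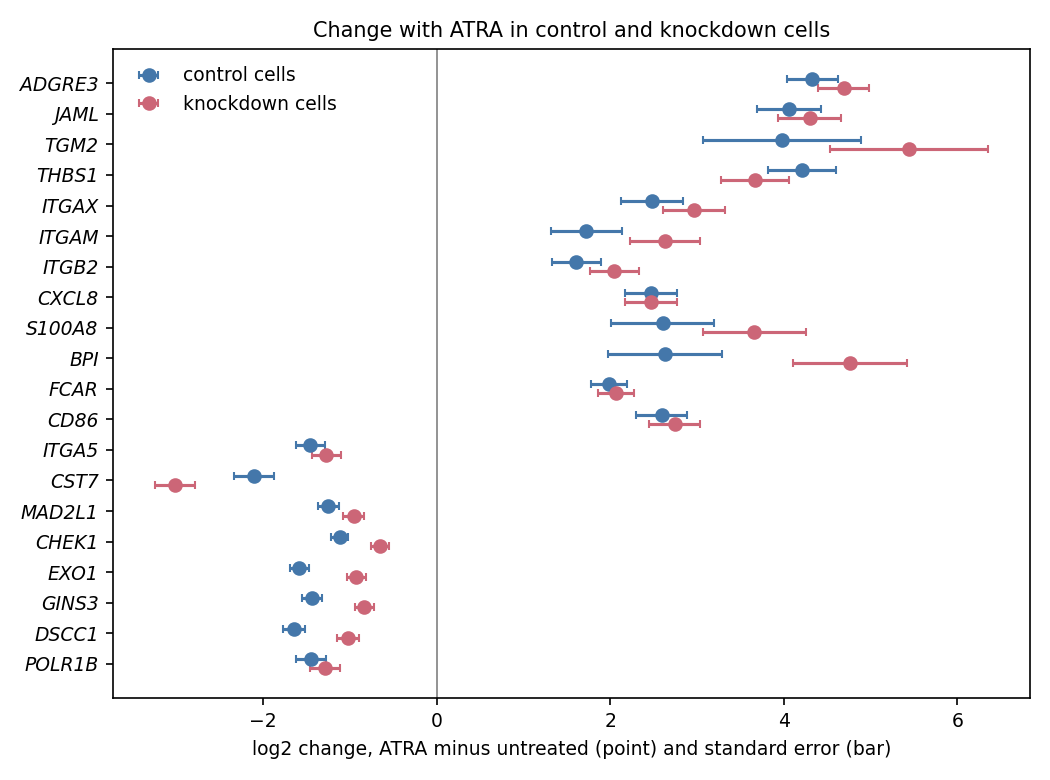
Log2 change with ATRA (x axis, ATRA minus untreated) of 20 genes named by the rule (y axis) in control cells (blue) and knockdown cells (red), 3 arrays per arm, with bars for the standard error. ADGRE3 lies at 4.33 and 4.69 and CST7 at -2.10 and -3.01 in control and knockdown cells.

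The second comparison asks the same of the knockdown cells. TGM2 rose by 5.44 on the log2 scale (SE 0.91), ADGRE3 by 4.69 (SE 0.29) and BPI, a bactericidal granule protein, by 4.76 (SE 0.65). CLC, the protein of Charcot-Leyden crystals, rose by 5.21 (SE 0.67), ALOX5AP, which serves leukotriene synthesis, by 4.72 (SE 0.66) and the purine receptor P2RY13 by 4.47 (SE 0.61). CXCL10, a chemokine induced by interferon, rose by 4.43 (SE 0.88; 3.25 without untreated shRNA2 and 5.18 without untreated shRNA1 replicate 1). CST7 fell by 3.01 (SE 0.23), CTSG, a protease of primary granules, fell by 2.45 (SE 0.49), and CA8, NT5DC2 and TENT5C fell by 2.34 to 2.46. limma called 1854 genes higher and 2714 lower, with 6362 at an unadjusted p under 0.05, and 536 higher and 218 lower genes changed by at least 1 on the log2 scale. Of the 340 olfactory receptor genes, 7 were called higher and 2 lower in knockdown cells. Of the genes called in control cells, 1190 were called higher and 2369 lower here as well, where independent lists of these sizes would share 282.1 and 566.9, and 9 went opposite ways.

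In knockdown cells 31 of 45 S phase genes fell with ATRA, and 36 did adjusted over the list alone, with a mean of -0.52 (adjusted p = 1.28e-12; adjusted p = 0.14 with an estimated correlation). EXO1 fell by 0.93 (SE 0.11) and the replication kinase CDC7 fell by 0.87 (SE 0.11). Of the G2 and mitosis genes 32 of 38 fell and 33 did adjusted over the list alone (mean -0.65, adjusted p = 7.04e-13; adjusted p = 0.157 with an estimated correlation). Of the ribosome biogenesis genes 18 of 19 fell, also adjusted over the list alone (mean -0.87, adjusted p = 9.39e-11; adjusted p = 0.14 with an estimated correlation). Of the DNA damage response genes 10 of 19 fell and 1, the kinase ATM, rose, also adjusted over the list alone (mean -0.33, adjusted p = 0.00284; adjusted p = 0.14 with an estimated correlation). Of the interferon response genes 16 of 25 rose and 19 did adjusted over the list alone (mean 1.83, adjusted p = 9.49e-12; adjusted p = 0.168 with an estimated correlation).

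Of the oxidase and neutrophil receptors 13 of 16 rose in knockdown cells and 14 did adjusted over the list alone (mean 1.06, adjusted p = 1.33e-08; adjusted p = 0.14 with an estimated correlation), among them CYBB, the catalytic subunit of the oxidase, at 1.48 (SE 0.22). Of the integrins 6 rose and 1 fell among 16, and 7 and 1 did adjusted over the list alone (mean 0.70, adjusted p = 0.00386; adjusted p = 0.14 with an estimated correlation), with ITGAX at 2.96 (SE 0.36) and ITGAM at 2.63 (SE 0.41). Autophagy and lysosome genes had a mean of 0.66 (adjusted p = 1.57e-07; adjusted p = 0.14 with an estimated correlation), chemokines and cytokines 0.97 (adjusted p = 5.1e-05; 0.14 with an estimated correlation), retinoid targets 1.29 (adjusted p = 0.00284; 0.14 with an estimated correlation) and apoptosis genes 0.43 (adjusted p = 0.00567; 0.168 with an estimated correlation). Monocyte and macrophage markers had a mean of 0.47 (adjusted p = 0.0211; 0.14 with an estimated correlation), myeloid transcription factors 0.47 (adjusted p = 0.0273; 0.174 with an estimated correlation) and secondary and tertiary granules 0.75 (adjusted p = 0.0299; 0.14 with an estimated correlation). Of the 18 monocyte and macrophage markers 5 rose and 0 fell, and of the 22 myeloid transcription factors 8 rose and 5 fell. Of the 19 secondary and tertiary granule genes 4 rose and 1 fell, with a median of 0.126. The calls of secondary and tertiary granules and of myeloid transcription factors ended without the shRNA1 replicate 2 ATRA array (adjusted p = 0.084 and 0.064), and the former also without the untreated shRNA1 replicate 1 array (0.0578) or without the lowest 33.3% of genes (0.135). That of monocyte and macrophage markers ended without the shRNA2 ATRA array (0.053).

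The third comparison asks how knockdown cells differ from control cells before ATRA. Integrins were lower in untreated knockdown cells, with a mean difference of -0.29 over 16 genes, of which 4 were higher (adjusted p = 0.0173; adjusted p = 0.822 with an estimated correlation). ITGAM differed by -1.12 (SE 0.41; -0.55 without untreated scrambled replicate 2) and ITGAX, another alpha subunit of leukocyte integrins, by -1.01 (SE 0.36; -0.47 without that array). Autophagy and lysosome genes differed by a mean of -0.16 (adjusted p = 0.0169; adjusted p = 0.822 with an estimated correlation) and apoptosis genes by -0.14 (adjusted p = 0.0463; adjusted p = 0.822 with an estimated correlation). G2 and mitosis genes were higher by a mean of 0.09, with 32 of 38 positive, and ribosome biogenesis genes by 0.13, with 17 of 19 positive (adjusted p = 0.0169 each; adjusted p = 0.825 each with an estimated correlation). Adjusted over the list alone, none of the members of these 5 lists was called. No gene passed limma's test (0 of 18404, smallest adjusted p = 0.999), and 727 had an unadjusted p under 0.05. The smallest p values belonged to ROR2, a receptor kinase (-0.74, SE 0.14), PCDHB4 (-0.62, SE 0.12) and INSIG1, a brake on sterol synthesis (-0.80, SE 0.14) among lower genes, and to OR2T10, RAB6B and PDP1 among higher genes, all with an adjusted p of 0.999.

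Without the untreated scrambled replicate 2 array, which stood apart on principal component 1, the mean difference was -0.12 for integrins (adjusted p = 0.445), and 0.04 for ribosome biogenesis, -0.02 for autophagy and lysosome and -0.03 for apoptosis genes (adjusted p = 0.811 each). Without untreated shRNA1 replicate 1 the adjusted p lay between 0.0529 and 0.0662 for all 5 lists, without untreated shRNA2 it was 0.439 for integrins and 0.502 for apoptosis (mean -0.09), and without untreated scrambled replicate 1 it was 0.893 for G2 and mitosis (mean 0.01) and 0.0524 for ribosome biogenesis. Other means grew without 1 array, to -0.22 for apoptosis and -0.26 for autophagy and lysosome without untreated scrambled replicate 1, and to 0.14 for G2 and mitosis and 0.20 for ribosome biogenesis without untreated wild type cells. The apoptosis call also ended without any of the ATRA arrays of wild type (0.0628), scrambled replicate 1 (0.0505), scrambled replicate 2 (0.0626) or shRNA1 replicate 1 (0.0535). Oxidase and neutrophil receptors (mean -0.12, adjusted p = 0.255) passed at -0.27 without untreated scrambled replicate 1 (adjusted p = 0.00264) and at -0.19 without untreated shRNA1 replicate 2 (adjusted p = 0.0278).

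The fourth comparison asks how knockdown cells differ from control cells after ATRA. DNA2, a nuclease and helicase of replicating DNA (probe set 7934026), was 1.73-fold higher, at 9.84 ± 0.12 against 9.05 ± 0.15 (SD, n = 3 each), with a log2 difference of 0.79 (SE 0.11, adjusted p = 0.0362). EXO1 (probe set 7910997) was higher by 0.74 (SE 0.11, adjusted p = 0.042) and ORC6, a subunit of the origin recognition complex (probe set 7995354), by 0.51 (SE 0.07, adjusted p = 0.0362). FIGNL1 and MMS22L, which serve DNA repair by recombination, were higher by 0.64 (SE 0.08) and 0.62 (SE 0.09), each with an adjusted p of 0.0362. AASDH, AFG2A, ST7 and the kinase STK39 were higher by 0.55 to 0.66. MAGEA8, a member of a gene family with shared sequence and therefore uncertain, was the only lower gene, at -0.53 (SE 0.07, adjusted p = 0.0362). limma called 10 genes higher and 1 lower, and 5171 had an unadjusted p under 0.05. The tenth higher gene was CPSF6 at 0.54 (adjusted p = 0.0362), which lies outside the rule for named genes and was chosen after its values were seen.

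**Figure D3:**
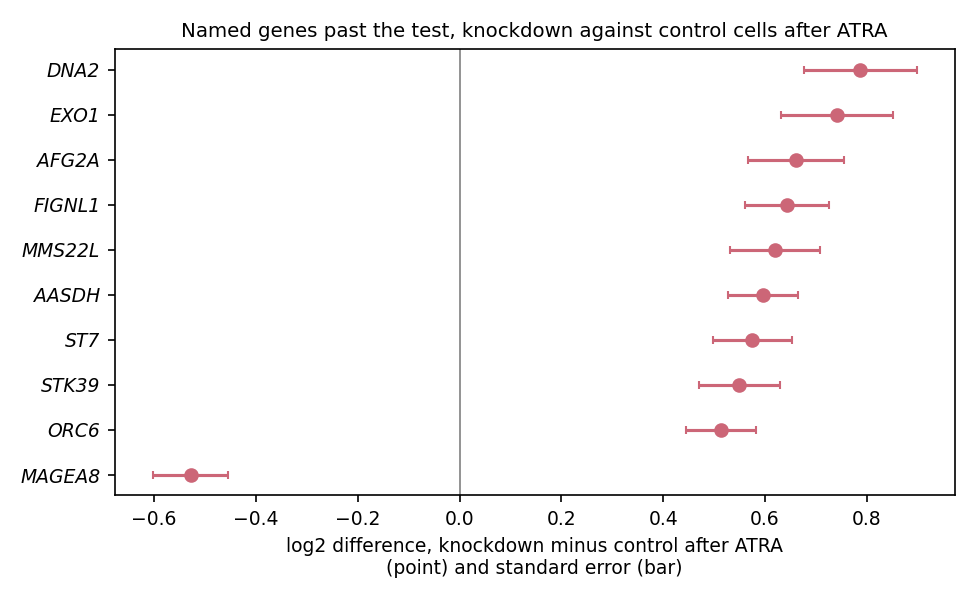
Log2 difference between knockdown and control cells after ATRA (x axis, knockdown minus control, 3 arrays each) of 10 of the 11 genes past the test (y axis), with points for the difference and bars for the standard error, and without CPSF6. The 9 higher genes lie between 0.51 and 0.79 and MAGEA8 at -0.53.

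The 11 calls lie close to the threshold (smallest adjusted p = 0.0336), and their number changed when 1 array was left out, also with untreated arrays, which enter this comparison only through the shared variance. No gene was called when the wild type untreated, shRNA1 replicate 1 untreated, shRNA1 replicate 2 untreated, scrambled replicate 2 ATRA, shRNA1 replicate 1 ATRA or shRNA2 ATRA array was left out, 1 without shRNA1 replicate 2 ATRA and 3 without wild type ATRA (0 of the 11 among them in either), and 8 without scrambled replicate 1 untreated (7 of the 11), while EXO1 kept a difference of 0.67 to 0.80 over these fits. Without the untreated scrambled replicate 2 array 701 genes were called, all 11 among them, without scrambled replicate 1 ATRA 78, and without untreated shRNA2 43. With all 12 arrays, 404 genes were called after median centring, 696 with array weights, 63 without the lowest 33.3% of genes, 28 with a trended and robust variance and 24 after quantile normalization.

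As groups, all 45 S phase genes were higher in knockdown than control cells after ATRA, with a mean of 0.51 (adjusted p = 1.68e-25; adjusted p = 0.0995 with an estimated correlation). ORC6 passed limma's test over all genes, and 39 of the 45 did adjusted over the list alone. The list mean was 9.76 ± 0.05 in knockdown and 9.25 ± 0.19 in control arrays after ATRA, and 10.28 ± 0.05 and 10.27 ± 0.04 before it (SD, n = 3 each). DNA damage response genes were higher by a mean of 0.43, with 18 of 19 positive, 1 past the test over all genes and 13 higher and 1 lower adjusted over the list alone (adjusted p = 3.07e-09; adjusted p = 0.0685 with an estimated correlation). The repair gene RAD54L differed by 0.60 (SE 0.10, adjusted p = 0.0506) and the helicase BRIP1 by 0.80 (SE 0.16, adjusted p = 0.0539). G2 and mitosis genes were higher by 0.22, with 38 of 38 positive (29 after quantile normalization) and 4 adjusted over the list alone (adjusted p = 1.03e-05; adjusted p = 0.652 with an estimated correlation), and by 0.10 without the shRNA2 ATRA array, with 25 of 38 positive (adjusted p = 0.0442). FOXM1, a transcription factor of mitotic genes, differed by 0.56 (SE 0.13, adjusted p = 0.0555). Ribosome biogenesis genes were higher by 0.34, with 19 of 19 positive and 0 adjusted over the list alone (adjusted p = 6.97e-06; adjusted p = 0.464 with an estimated correlation), and by 0.17 without the wild type ATRA array (adjusted p = 0.0033).

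**Figure D4:**
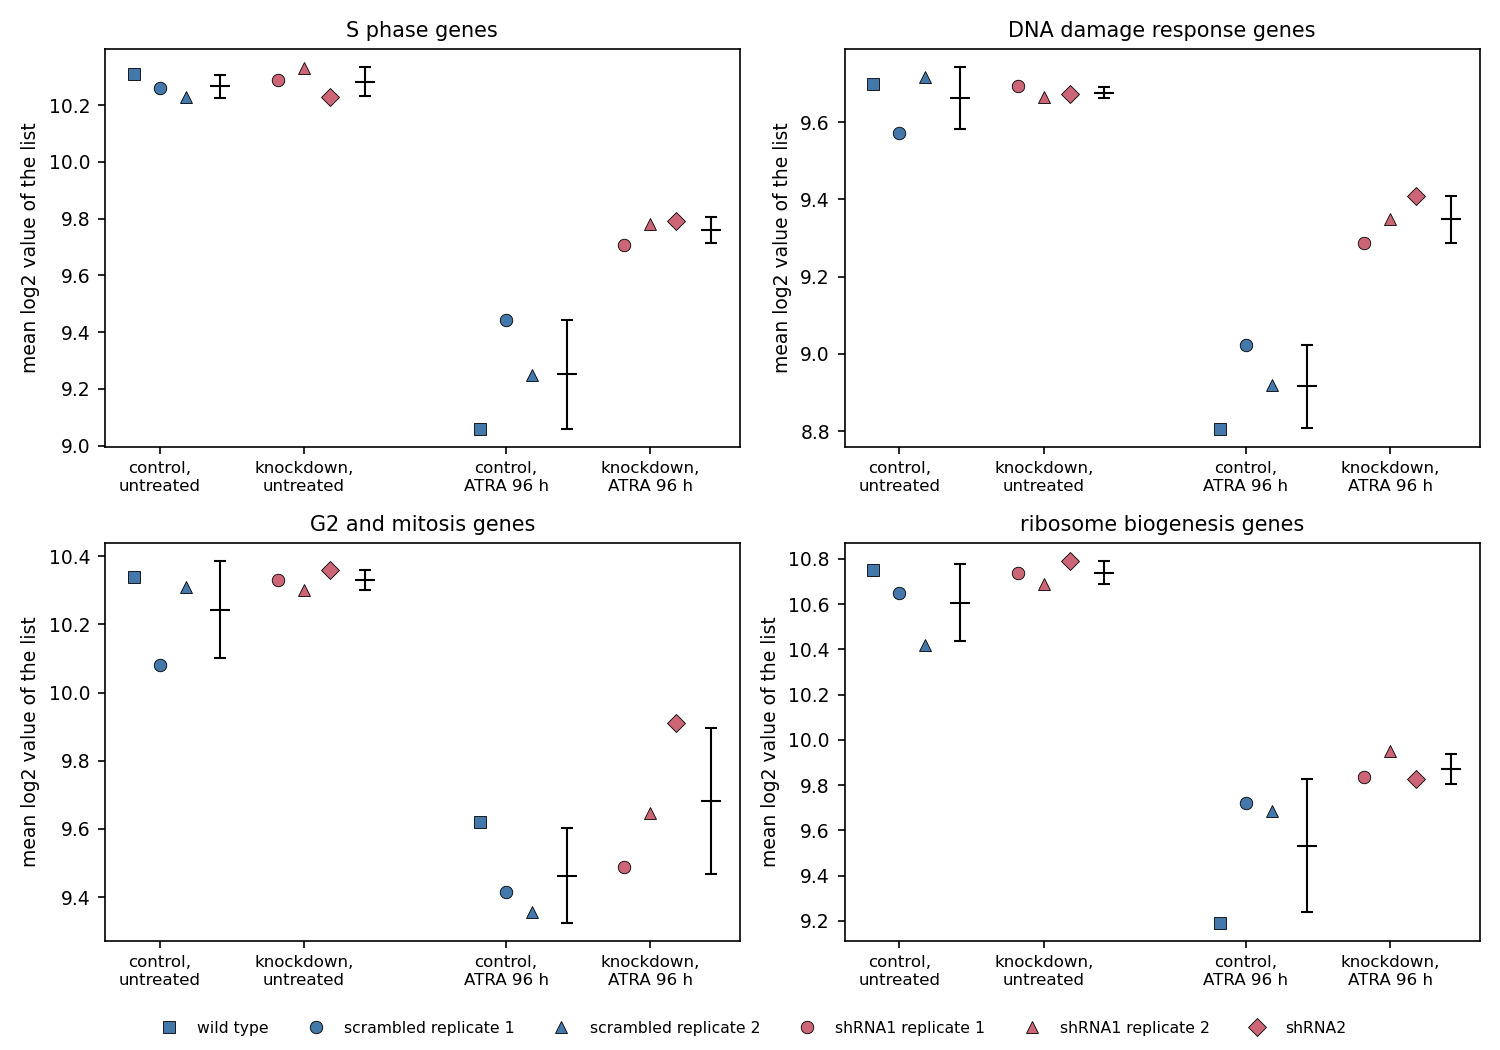
Mean log2 value of the S phase, DNA damage response, G2 and mitosis and ribosome biogenesis genes (y axes) in each of the 12 arrays by arm (x axis), with blue control and red knockdown arrays and black bars for the arm mean and SD. After ATRA the S phase mean is 9.71 to 9.79 in the 3 knockdown arrays and 9.06 to 9.44 in the 3 control arrays.

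Secondary and tertiary granule genes were lower in knockdown cells after ATRA, with a mean of -0.41 over 19 genes, 1 of them positive and 1 lower adjusted over the list alone (adjusted p = 0.0187; adjusted p = 0.127 with an estimated correlation). HP, which encodes haptoglobin, differed by -1.69 (SE 0.59, adjusted p = 0.104; -2.38 without wild type ATRA) and LCN2, an iron-scavenging granule protein, by -0.32 (SE 0.08, adjusted p = 0.0607). LCN2 lay at 7.15 to 7.62 in all 12 arrays, below the array medians of 7.73 to 7.81. The closing test of a shift that depends on level did not cover this granule list. The call of secondary and tertiary granules ended without the scrambled replicate 1 ATRA array (adjusted p = 0.0503) or the shRNA1 replicate 1 ATRA array (0.0502). Monocyte and macrophage markers were lower by a mean of -0.20, with 1 of 18 positive and 1 lower adjusted over the list alone (adjusted p = 0.00268; adjusted p = 0.0995 with an estimated correlation). Lymphoid markers were lower by -0.15, with 3 of 14 positive and 3 lower adjusted over the list alone (adjusted p = 0.0245; adjusted p = 0.119 with an estimated correlation). The scavenger receptor MARCO differed by -0.39 (SE 0.08, adjusted p = 0.0539) and the T cell kinase LCK by -0.44 (SE 0.08, adjusted p = 0.052). The 340 olfactory receptor genes had a median difference of -0.12 in the same comparison, and the lymphoid call ended after quantile normalization (adjusted p = 0.0856) and without the shRNA2 arrays (0.0586). The interferon response list, at a mean of -0.28 (adjusted p = 0.258), turned to 0.32 without the shRNA1 replicate 1 ATRA array (adjusted p = 0.0502) and to 0.09 without scrambled replicate 1 ATRA (adjusted p = 0.835). It was -0.43 without scrambled replicate 2 ATRA (adjusted p = 0.0528), and passed without the wild type ATRA array (-0.49, adjusted p = 0.0192), the shRNA1 replicate 2 ATRA array (-0.58, adjusted p = 0.00435) or the shRNA2 ATRA array (-0.58, adjusted p = 0.0111).

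**Figure D5:**
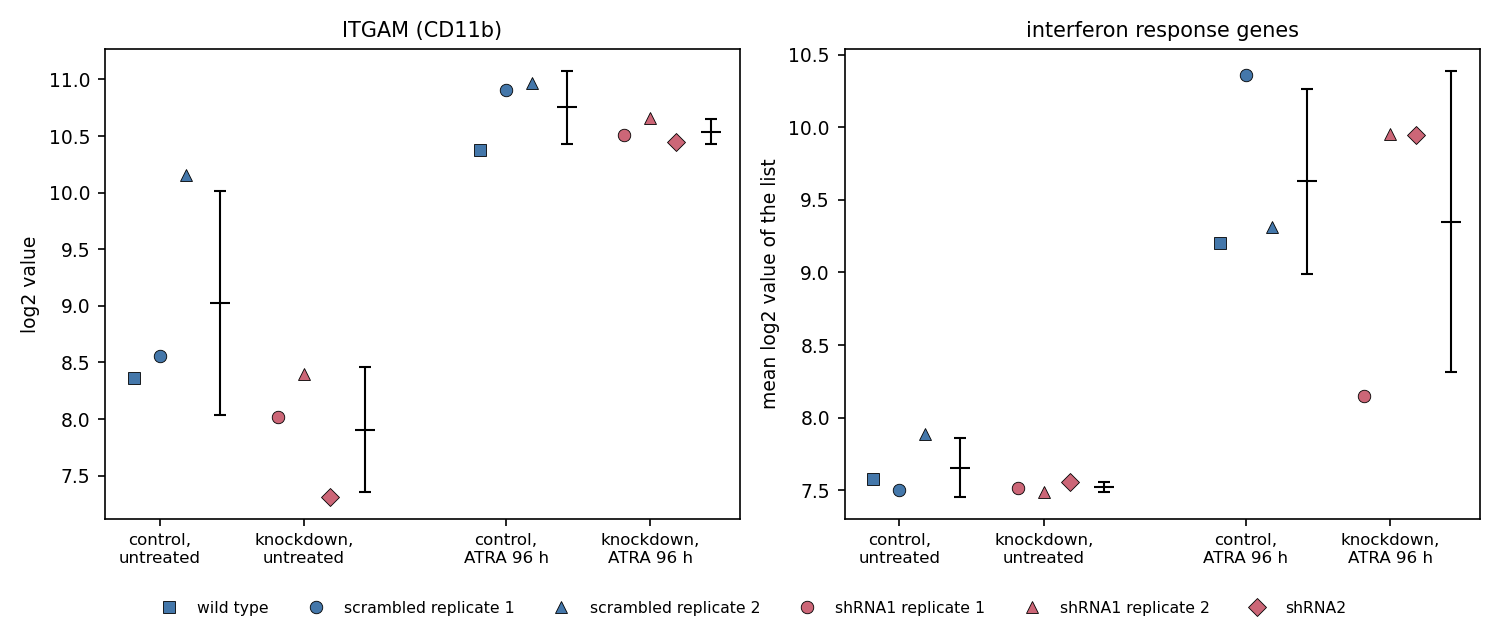
Log2 value of ITGAM (left y axis) and mean log2 value of the interferon response genes (right y axis) in each of the 12 arrays by arm (x axes), with blue control and red knockdown arrays and black bars for the arm mean and SD. ITGAM is 10.16 in the untreated scrambled replicate 2 array, and the interferon mean is 8.15 in the shRNA1 replicate 1 ATRA array against 9.21 to 10.36 in the other ATRA arrays.

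The fifth comparison asks whether the ATRA response itself differs between knockdown and control cells. S phase genes fell less in knockdown cells, by a mean of 0.49 with 45 of 45 positive (adjusted p = 5.08e-22; adjusted p = 0.164 with an estimated correlation). Adjusted over the list alone 26 of the 45 were called, among them RFC2, a subunit of the clamp loader (0.48, SE 0.11), and the DNA ligase LIG1 (0.56, SE 0.14), each at an adjusted p of 0.271 over all genes. DNA damage response genes differed by 0.42, with 17 of 19 positive, and 10 higher and 1 lower adjusted over the list alone (adjusted p = 2.26e-07; adjusted p = 0.131 with an estimated correlation). No gene passed limma's test of the difference (0 of 18404, smallest adjusted p = 0.271), and 2815 had an unadjusted p under 0.05. The smallest p values belonged to AASDH, DNA2, STK39, TUBGCP5 and EMC3-AS1 with positive differences of 0.57 to 0.85, and to MAGEA8, OLIG3, MYT1, P4HA2 and OR2T10 with differences of -0.63 to -0.53. G2 and mitosis genes differed by 0.13 (adjusted p = 0.0239; adjusted p = 0.735 with an estimated correlation), ribosome biogenesis genes by 0.21 (adjusted p = 0.0212; adjusted p = 0.67 with an estimated correlation) and monocyte and macrophage markers by -0.15 (adjusted p = 0.0185; adjusted p = 0.176 with an estimated correlation). The olfactory receptor genes had a median difference of -0.10.

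Single arrays decided some of these calls. The G2 and mitosis difference was 0.02 without the shRNA2 ATRA array (adjusted p = 0.613), and its call also ended without the wild type untreated (mean 0.08, adjusted p = 0.18), scrambled replicate 2 untreated (adjusted p = 0.141), scrambled replicate 1 ATRA (adjusted p = 0.16) or scrambled replicate 2 ATRA array (mean 0.08, adjusted p = 0.18). It was 0.21 without scrambled replicate 1 untreated or without wild type ATRA, and 0.23 without shRNA1 replicate 1 ATRA. The ribosome biogenesis difference was 0.04 without the wild type ATRA array (adjusted p = 0.501), and its call also ended without the wild type untreated (mean 0.13, adjusted p = 0.18), scrambled replicate 1 untreated (adjusted p = 0.0518) or shRNA1 replicate 2 ATRA array (adjusted p = 0.0582). The call of monocyte and macrophage markers ended without the shRNA1 replicate 1 ATRA array (mean -0.10, adjusted p = 0.0777). Without single arrays, lists not past the test in the full fit passed it: interferon response without shRNA1 replicate 1 ATRA (mean 0.46, adjusted p = 0.0149), autophagy and lysosome without scrambled replicate 1 untreated (0.20, adjusted p = 0.0393), and coagulation and fibrinolysis without shRNA1 replicate 1 untreated (-0.43, adjusted p = 0.0376). In several lists, none past its test, the mean, median and test direction differed in sign, as for CDK inhibitors and G1 (mean -0.04, median 0.03) and progenitor and stem markers (mean -0.17, median 0.08) with ATRA in control cells, and chemokines and cytokines (mean 0.02, median -0.14) in the difference.

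The size of the response was compared on 1759 genes that moved by at least 1 on the log2 scale in the wild type pair, 618 up and 1141 down. Over them, the change signed by the wild type direction averaged 1.07 in scrambled replicate 1, 0.75 in scrambled replicate 2, 0.95 and 0.94 in the shRNA1 replicates and 1.11 in shRNA2. The ratio of knockdown to scrambled cells was 1.10 ± 0.104 (SD over shRNA1 replicates 1 and 2 and shRNA2), with no test. It was 1.27 for the genes that went up in the wild type pair and 0.956 for those that went down. The genes that went up changed by 1.524 in scrambled replicate 1 and 0.801 in scrambled replicate 2. They changed by 1.274 and 1.471 in the shRNA1 replicates and 1.691 in shRNA2. The higher ratio for these genes thus rests on scrambled replicate 2, whose untreated array stood apart. In the same order, the genes that went down changed by -0.82, -0.72, -0.77, -0.65 and -0.79. Over all 1759 genes, the ratio was 0.932 without scrambled replicate 2 and 1.34 without scrambled replicate 1.

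The agreement of the shRNAs was compared on the 200 genes with the smallest p for shRNA1 against scrambled cells. After ATRA, shRNA2 differed from wild type cells in the same direction for 165 of them (82.5%, exact Clopper-Pearson interval 76.5 to 87.5%). Before ATRA this held for 87 (43.5%, interval 36.5 to 50.7%). These comparisons share no array, genes are not independent replicates, and wild type cells carry no vector.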

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

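The tests of array scaling, of mixed cells and of other splits of the arrays given here were chosen only after the results were seen. Each list below was singled out because the test of the difference in ATRA response between knockdown and control cells passed its threshold.

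The S phase list differed by a mean of 0.492 on the log2 scale (adjusted p = 5.08e-22, camera; adjusted p = 0.164 with an estimated correlation), with 45 of 45 genes positive, and the DNA damage response list by 0.418 (adjusted p = 2.26e-07; adjusted p = 0.131 with an estimated correlation). The ribosome biogenesis list differed by 0.207 (adjusted p = 0.0212; adjusted p = 0.67 with an estimated correlation), and was 0.04 without the wild type ATRA array and -0.04 without both wild type arrays. The G2 and mitosis list differed by 0.131 (adjusted p = 0.0239; adjusted p = 0.735 with an estimated correlation), but by 0.0154 without the shRNA2 ATRA array. The monocyte and macrophage markers differed by -0.154 (adjusted p = 0.0185; adjusted p = 0.176 with an estimated correlation), and by -0.10 without the shRNA1 replicate 1 ATRA array.

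S phase genes were higher in knockdown than control cells after ATRA by a mean of 0.508, and a scaling difference between arrays as the whole explanation is argued against by 0.442 after quantile normalization and by 0 of 10000 random lists matched on mean level reaching 0.508, though such lists had a median of 0.108 and reached 0.225. Undifferentiated cells left in the knockdown cultures are a candidate explanation that stays open. The share of RNA from untreated cells needed, solved on the linear scale, was 30.3 ± 3.08% for S phase genes, 15.7 ± 6.14% for other genes that fell in wild type cells and 5.97 ± 12% for genes that rose (SD, n = 3 arrays each), the last added after the second had been seen. The genes that rose ranged from -3.92% to 19.4% between arrays, so a mixture and a specific difference cannot be told apart by this test. A lasting effect of HOTAIRM1 knockdown and a difference between single-cell clones also remain open and untested, since HOTAIRM1 was not measured and each line is either control or knockdown.

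The 6 arrays compared can be split 3 against 3 in 10 ways, the real one included, too few for a share under 0.05. For ATRA in control cells 1 of the 10 splits, the real one, gave as many as 6644 genes, and the highest other gave 0. For ATRA in knockdown cells 1 of 10 gave as many as 4568, and the highest other gave 0. For knockdown against control after ATRA 1 of 10 gave as many as 11, and the highest other gave 7. For knockdown against control before ATRA and for the difference in response the real count was 0, which any split (10 of 10) must reach, so the splits say nothing there, and the highest other gave 1 in each.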

How the results depend on the processing

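Of 342 values of named genes, 281 kept their side of the threshold under all alternatives. Of 7931 comparisons with an alternative 206 lost and 93 gained a call and 0 reversed. A turn of direction was counted only where the main fit or the alternative had a call. All 47 values for knockdown against control before ATRA and all 47 for the difference in response were kept, with no gene called there in any fit. For knockdown against control after ATRA 27 of 57 were kept. Of 105 list results, 49 were kept by the same rule. The 21 lists had no call with an estimated correlation in any contrast. The counts of 0 for knockdown against control before ATRA and for the difference in response stayed at 0 under every alternative run, with limma throughout. Signal over background limits what the arrays show of dim genes. Where a result changed below, the cause was not tested, except that leaving out arrays lowers the number of samples and the added log2 threshold can only lower a count.

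For ATRA in control cells, against 6644 genes, 3460 were called without the wild type arrays, 2981 with scrambled against shRNA1 cells only and 893 with a log2 change of at least 1, and 4526 to 6646 when each array was left out in turn. After median centring 28.4% of the calls were higher, against 42.1%. For ATRA in knockdown cells, against 4568, 2318 were called without the shRNA2 arrays, 2361 with scrambled against shRNA1 only and 754 with a log2 change of at least 1, and 3428 to 4918 when each array was left out. For knockdown against control after ATRA, against 11, 0 were called on the 6 arrays compared alone, 0 without the wild type arrays, 0 without the shRNA2 arrays, 0 with scrambled against shRNA1 only and 0 with a log2 change of at least 1. Quantile normalization gave 24, of which 54.2% were higher against 90.9%, median centring 404, removal of the lowest 33.3% of genes 63, a trended and robust variance 28 and array weights 696, and leaving out each array gave 0 to 701.

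With each line as a block, 6061 genes were called for ATRA in control cells, 4398 for ATRA in knockdown cells and 0 for the difference. With replicate number as a block over scrambled and shRNA1 arrays, 0 were called for knockdown against control before ATRA and 0 after it. Deviations from the arm mean correlated between the states of a line at -0.173 in wild type, -0.108 and 0.193 in scrambled, 0.161 and 0.226 in shRNA1 and 0.119 in shRNA2 cells. Scrambled and shRNA1 arrays of the same number were compared by deviations from the mean of their own 2 arrays. These correlated at -0.053 untreated and -0.336 after ATRA, the same for both numbers, as 2 arrays deviate by mirror images. The main fit did not take the numbers as pairs. The changes per line, the size of the response and the line block did match untreated and ATRA arrays by replicate number. The negative correlations in wild type and scrambled replicate 1 give that match no support there. Line as a random block (consensus correlation 0.0354) kept all 11 genes. Each such line holds a single array per state, so this block cannot account for dependence between duplicates of the same cells.

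Against scrambled cells as the control of shRNA2, which shares arrays with the ranking, the agreement of the shRNAs was 97.5% after ATRA and 82.5% before it. The size ratio ran from 0.932 to 1.34 when each line was left out. The direction of the G2 and mitosis test before ATRA turned without untreated scrambled replicate 1 (mean 0.0058, adjusted p = 0.893; range over left-out arrays 0.0058 to 0.138). That of the interferon response difference turned without the shRNA1 replicate 1 ATRA array (0.459, adjusted p = 0.0149; range -0.442 to 0.459), and that of the ribosome biogenesis difference without the wild type arrays (-0.036, adjusted p = 0.829).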

Other observations

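The gene families and the tests of explanations in this part were chosen only after the results were seen. The limma calls, the camera list tests and quantile normalization were fixed before. Several families leaned to higher values in knockdown than control cells after ATRA, without any member past limma's test over all genes and with no test of the family, while genes above the lowest 33.3% had a median of 0.05. Means of random lists matched on level to the S phase genes had a median of 0.108 and reached 0.225. No lists were matched to these families, so smaller values below may reflect level alone. The aminoacyl-tRNA synthetases, which charge tRNAs for translation, were positive in 32 of 32 genes (29 after quantile normalization), with a median of 0.27. Nucleoporins, the proteins of the nuclear pore, were positive in 20 of 20 (19 after quantile normalization, median 0.29), and the condensin and cohesin subunits, which shape chromosomes, in 14 of 14 (13 after quantile normalization, median 0.24). All 8 Fanconi anaemia genes, which repair DNA crosslinks and of which 3 stand in a fixed list, were positive with a median of 0.45. Cytosolic ribosomal proteins were positive in 52 of 59 (51 after quantile normalization, median 0.14), NADH dehydrogenase subunits in 28 of 32 (21 after quantile normalization, median 0.15), proteasome subunits in 24 of 36 (19 after quantile normalization, median 0.09) and vacuolar ATPase subunits in 6 of 20 (median -0.09). With ATRA in control cells 21 of the 32 synthetases, 18 of the 20 nucleoporins, 22 of the 36 proteasome subunits and all 8 Fanconi anaemia genes fell past the test, and in knockdown cells 10, 16, 21 and 2 did, with no test of the difference between these counts.

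The interferon response genes rose by different amounts between samples. Their mean change with ATRA was 1.63 in wild type cells, 2.86 and 1.43 in scrambled replicates 1 and 2, 0.64 and 2.46 in shRNA1 replicates 1 and 2, and 2.39 in shRNA2 cells. IFIT1, an antiviral protein induced by interferon, lay at 6.99 in the shRNA1 replicate 1 array after ATRA and at 9.39 to 11.04 in the other ATRA arrays. IFI44L lay at 6.07 in the same array and at 7.98 to 11.10 in the others. IFIT3 and OAS1 were also lowest in that array, at 7.59 and 8.81. ISG15 lay little lower there, at 8.30 against 8.49 to 8.86. MX1 did not stand apart, at 6.32 against 6.31 to 6.66.

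The untreated scrambled replicate 2 array lay toward the ATRA arrays, and relative to the other untreated control arrays its retinoid targets were higher by 0.91, integrins by 0.51 and myeloid transcription factors by 0.46, while among lists that fall with ATRA, S phase genes differed by -0.05, ribosome biogenesis genes by -0.29 and G2 and mitosis genes by 0.10. An ATRA-treated sample under an untreated label is argued against by its S phase mean of 10.23, above the 9.79 of the highest ATRA array and at the level of the other untreated arrays (10.23 to 10.33). RNA of ATRA-treated cells mixed into the sample would give 1 share for all genes that move with ATRA, but the share was 10.4% for S phase genes (95% bootstrap interval 3.77 to 19.4%), 29.1% for genes that rose (25.4 to 32.5%) and 45.2% for other genes that fell (41.4 to 47.6%). The first form of this test compared only falling with rising genes and by its written criterion went with a mixture, although the intervals did not overlap, and the S phase share was made the deciding value after that had been seen. A culture that had started to mature may account for the pattern, and no biological explanation was tested.

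Of the marker lists of other cell types, 3 chosen because they were low in knockdown against control arrays after ATRA (monocyte, lymphoid and, not past its test at an adjusted p of 0.0805, erythroid) had a mean of -0.164, while progenitor and stem markers had -0.02 (adjusted p = 0.764). Unequal array distributions left by the authors' normalization, as the whole explanation, are argued against by a mean of -0.147 after quantile normalization. A shift across the array that depends on level stays open. Of 10000 random draws matched on mean level, 5 lay at or below the lists (median -0.0685), but 0 had been asked for to exclude it, and the draws take genes as independent. Olfactory receptor genes, used in a first form of this test that went with such a shift (median -0.121), lie near the floor and say little of the 23 members above the lowest 33.3% of genes, whose mean was -0.192, against -0.142 for the 21 within it.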
